A study of Xenopus tropicalis with 21 samples.

How the data were processed

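Liver RNA of mature female Xenopus tropicalis was sequenced as 75 bp reads on an Illumina GAIIx from stranded poly(A) libraries made from 15 mg of liver, per the labels' protocols. The labels place 21 biological replicates in 4 groups by generation and by the treatment of the F0 ancestors: 5 F1 control, 6 F1 BaP, 5 F2 control and 5 F2 BaP frogs. The F0 ancestors of the BaP groups had been kept in benzo[a]pyrene at 50 ng/L, and the frogs sequenced had not.

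The submitters' processing notes list Trimmomatic 0.32.1, HISAT2, Cufflinks 0.0.7 and Cuffdiff 0.0.7, with no role or order. Parameters are not given in the sources used here. Per the file headers, the 2 deposited tables are Cuffdiff comparisons of BaP with control, 1 for F1 and 1 for F2, over the same 20288 rows. The deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) is 1 value per group and gene, made by the authors from all libraries of the group. The deposited log2 fold change is BaP over control with no pseudocount, and it is infinite where a group is listed at 0. The authors' p-value and q-value (the p adjusted for multiple tests) stand beside it, and the smallest p was 5e-05 in both tables, reached by 95 tests in F1 and 81 in F2. The deposited test statistic is a score that does not give the deposited p under a normal distribution: the z value of the p was a median 2.29 times the statistic in both tables.

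Of the rows, 20077 held 1 gene name, 143 held several and 68 had none. All 20077 names were found in the gene table of assembly UCB_Xtro_10.0, and for 18346 of them (91.4%) both ends were identical, so positions are given on that assembly, counted from 1. The authors tested 12426 rows in F1 and 12236 in F2. The tables mark 7847 rows of F1 and 8039 of F2 as not tested. A further 15 rows in F1 and 12 in F2 are marked as having too much data, and 1 in F2 as failed. Rows with too much data include the albumin, vitellogenin A2 and hemoglobin genes alb, vtga2 and hba1, and a group value of 0 there is not an expression level. Neither table holds values of single libraries, so the depth of each library is unknown and no spread between frogs could be computed. Precision is therefore given by the authors' q, which rests on a test not repeated here.

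The choices below were fixed before the data were examined, except where stated. A gene was called where the authors' test was done and q was under 0.05. The overlap of calls was tested with Fisher's exact test, one-sided, among 11679 genes tested in both tables. Fold changes were correlated across genes that were tested in both tables, had finite values and reached an FPKM of 1 in at least 1 group of each table. The change in F2 minus that in F1 was divided by its standard error, which was taken from each deposited log2 fold change and p, and the normal p was adjusted by Benjamini-Hochberg. No SD accompanies these values, because the tables hold none. Named genes were the 10 called genes with the largest rise and the 10 with the largest fall per generation, up to 4 called members of each list that passed or held at least 3 calls, up to 10 genes called in both generations, 17 genes set in advance where tested, and the 6 genes with the smallest p of the difference. The first part of that rule took only genes with a symbol of their own, a finite fold change and an FPKM of 1 in the higher group. Of the genes so chosen, 1 is not reported here, though it stays in the tests and counts.

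A total of 40 gene lists, written from textbook knowledge, were tested with cameraPR of limma 3.58.1 in R 4.3.3. The input was the normal quantile of the authors' p, signed by the direction of change, with a preset correlation between genes of 0.01 and at least 5 tested members. P-values were adjusted by Benjamini-Hochberg over the lists of a generation. A correlation between genes could not be estimated without libraries, so 0.05 was tried as an alternative. The median log2 fold change of each list was also set against 10000 random lists of genes outside it, each drawn from the 200 genes nearest in mean FPKM. The smallest two-sided p that these lists can give is 0.0002. Because only 50 genes outside the ribosomal and oxidative phosphorylation lists reached 1000 FPKM in F1, such lists match the ribosomal proteins poorly, and membership was instead shuffled within classes of FPKM, a test added after the data were seen.

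Other alternatives were q under 0.01 or 0.1, a fold minimum of 1.5, q-values recomputed, rows with a single symbol, centred fold changes, other FPKM minimums and pseudocounts, and standard errors from the test statistic. After the data were seen, 7 lists of other tissues were left out of the counts of calls, the difference was scaled to its own spread, and 3 lists were written for the observations at the end. Leaving out single frogs was planned but needs values of single libraries. On simulated data for the F1 genes, cameraPR recovered 119 of 120 lists shifted by 1 SD of z and called 4 of 523 unshifted ones. The simulated z were independent between genes, so these rates do not cover lists whose genes vary together. In a simulation of the difference between generations over 11677 genes, 94 of 200 genes with a true log2 difference of 2 were recovered, with 2 false calls. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.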

Results

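Liver transcripts were measured in mature females of the tropical clawed frog, Xenopus tropicalis, from the F1 and F2 generations. Their F0 ancestors had lived from tadpole to adult either as controls or in benzo[a]pyrene (BaP) at 50 ng/L. BaP is a polycyclic aromatic hydrocarbon that binds the aryl hydrocarbon receptor. The F1 and F2 frogs themselves were not exposed, and "BaP" below names the lineage. There were 5 F1 control, 6 F1 BaP, 5 F2 control and 5 F2 BaP frogs. Each generation was compared with its own controls, to find out which liver genes differ in descendants of exposed frogs and whether they are shared by both generations. Values are group FPKM and log2 fold changes (BaP over control) from the authors' deposited tables, which give no value per frog, so no SD can be printed and the depth of each library is unknown. A gene was called at q under 0.05.

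In F1 liver, genes of cholesterol synthesis were lower in the BaP lineage. Interferon response genes, ribosomal protein genes and oxidative phosphorylation genes were higher. The authors' deposited table for F1 called 207 of 12426 tested genes (1.67%), of which 76 were higher and 131 lower. Unadjusted p was under 0.05 for 1107 genes (8.91% of tests).

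Of the 40 lists set in advance, cholesterol synthesis had the smallest p in F1: 15 of its 30 tested genes fell and none rose. The median log2 fold change was -1.23 (adjusted p = 1.49e-27, limma cameraPR). Adjusted over the list alone, 20 members fell and 1 rose. Squalene epoxidase, sqle (chromosome 6, 143392404 to 143401523), had a log2 fold change of -5.34 in the authors' deposited table, with 2.66 FPKM in controls, 0.0656 in BaP frogs and q = 0.0154. The sterol demethylation enzymes msmo1 and cyp51a1 fell by 3.90 and 3.74 there, both with q = 0.00654, the smallest q in the authors' deposited table for F1. The synthase gene hmgcs1, which acts early in the pathway, had 71.5 FPKM in controls and 12.4 in BaP frogs in the authors' deposited table (log2 fold change -2.53, q = 0.0191). The rate-limiting enzyme of bile acid synthesis, cyp7a1, had -2.96 in the authors' deposited table (q = 0.00654) and was the 1 called gene among 24 tested of bile acid metabolism (list adjusted p = 0.776).

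Interferon response genes were higher in F1 BaP livers: 32 of 37 tested members had a positive log2 fold change, with a median of 0.86 (adjusted p = 6.98e-12, limma cameraPR). Of these, 4 were called, all higher, and 9 rose when adjusted over the list alone. The antiviral GTPase gene mx1 (chromosome 2, 10660888 to 10703222) rose from 6.29 to 55.0 FPKM in the authors' deposited table (log2 fold change 3.13, q = 0.00654), and cmpk2, samd9l and the RNA sensor gene ddx58 followed with 2.05, 2.02 and 1.54. Antigen processing and presentation genes rose as a list (16 of 20 values above 0, median 0.38, adjusted p = 0.00217, limma cameraPR). Its 1 called member, the peptide transporter gene tap1, had a log2 fold change of 1.38 in the authors' deposited table (q = 0.0279). The RNA helicase gene mov10 (2.24), the interleukin-18 binding protein gene il18bp (2.70) and mr1-like (2.14) were also among the largest rises in the authors' deposited table.

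Ribosomal protein genes were higher together in F1: 78 of 80 values were above 0 and the median log2 fold change was 0.71 (adjusted p = 2.14e-12, limma cameraPR). None of the 80 was called in the authors' Cuffdiff table, where 9 had an unadjusted p under 0.05. Among oxidative phosphorylation genes 69 of 74 values were above 0, with a median of 0.47 (adjusted p = 4.34e-13). The ATP synthase subunit gene atp5mc1, with a log2 fold change of 1.25 in the authors' deposited table (q = 0.0320), was called, and 4 genes rose when adjusted over the list alone. Proteasome genes also rose as a list (37 of 43 values above 0, median 0.26, adjusted p = 0.000109), with 0 called by Cuffdiff, 6 at an unadjusted p under 0.05 and 2 when adjusted over the list alone. Fold changes in F1 grew with expression: outside the ribosomal and oxidative phosphorylation lists, the median was 0.01 for 6789 genes with a mean of 1 to 10 FPKM and 0.42 for 50 genes at 1000 FPKM or more.

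Gluconeogenesis genes were higher in F1, with 24 of 30 values above 0 and a median of 0.19 (adjusted p = 0.00158, limma cameraPR), although this median did not stand apart from random lists matched on expression (adjusted p = 0.2). The called members were pck1, which encodes the cytosolic enzyme that commits carbon to glucose synthesis, and igfbp1. In the authors' deposited table pck1 (chromosome 10, 5408168 to 5414677) went from 0.167 to 6.10 FPKM (log2 fold change 5.19, q = 0.00654) and igfbp1 from 5.24 to 27.7 FPKM (log2 fold change 2.40, q = 0.00654). Among 57 fatty acid oxidation genes 1 was called higher and 3 lower (list adjusted p = 0.641). These were vnn1 with 1.71, the hormone-sensitive lipase gene lipe with -1.46, slc27a4 with -1.26 and acot12 with -1.02 in the authors' deposited table. In the heat shock list 3 of 40 genes were called, all lower (list adjusted p = 0.98): hsp70 had -2.42, hsp90aa1.2 -1.50 and the collagen chaperone gene serpinh1 -1.45 in the authors' deposited table.

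Markers of other tissues moved in the same F1 comparison. Skeletal muscle markers were lower (12 of 12 values below 0, median -1.17, adjusted p = 4.45e-07, limma cameraPR), and 3 were called: acta1, tnnt1 and ckm, with -3.39, -3.06 and -1.52 in the authors' deposited table. Pancreas markers were higher (12 of 15 values above 0, adjusted p = 3.56e-06), with 3 called and 7 higher at an unadjusted p under 0.05. The most abundant members, the amylase genes amy2a and amy2b, had -0.04 and 0.22 in the authors' deposited table, neither called (chosen after their values were seen). The chymotrypsin gene ctrc had 0.433 FPKM in controls and 14.4 in BaP frogs in the authors' deposited table (log2 fold change 5.06, q = 0.0279), and ctrb2 and cpb1 were listed at 0 in controls and at 1.17 and 1.12 FPKM in BaP frogs. Erythrocyte markers were higher (30 of 33 values above 0, median 0.31, adjusted p = 6.4e-06), and hbd was called with 1.17 in the authors' deposited table. Pigment cell markers were lower (9 of 11 values below 0, median -0.79, adjusted p = 0.000516), with 0 called by Cuffdiff, 6 lower at an unadjusted p under 0.05 and 5 lower when adjusted over the list alone. Without the members of the 7 lists of other tissues, an alternative chosen after seeing the data, 198 genes were called in F1, 71 higher and 127 lower. These still include 20 motile cilium genes, all lower, from a list written after the calls were seen and described under the other observations.

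Of the remaining F1 genes with large changes, cnbd2 (5.58) had the largest finite rise of a called gene with a symbol in the authors' deposited table, and s1pr3 (-4.47), tgm4 (-3.25), pbxip1 (-3.17) and gtf2e1.2 (-2.60) were among the largest falls. Genes of xenobiotic oxidation, the classical response to BaP itself, did not pass: 0 of 38 were called by Cuffdiff and 1 had an unadjusted p under 0.05 (list adjusted p = 0.98). The BaP-metabolising enzyme gene cyp1a1 had a log2 fold change of 0.18 and the receptor gene ahr one of 0.38 in the authors' deposited table for F1. Lists for oxidative stress and NRF2 (adjusted p = 0.0134) and for acute phase, complement and coagulation (adjusted p = 0.0223) rose with 0 called by Cuffdiff, 3 and 6 at an unadjusted p under 0.05. Both lost their call at a preset correlation of 0.05 (adjusted p = 0.157 and 0.253), and the acute phase median of 0.16 did not stand apart from random lists matched on expression, at 0.19 (adjusted p = 0.89). In all, 13 of 40 lists passed in F1.

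In F2 liver, cholesterol synthesis genes were higher in the BaP lineage, and the genes that fell included fos, egr1, dusp1 and igf1. The authors' deposited table for F2 called 162 of 12236 tested genes (1.32%), 97 higher and 65 lower. Unadjusted p was under 0.05 for 1089 genes (8.9% of tests).

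Cholesterol synthesis again had the smallest p of the lists, in the other direction: 6 of 31 tested genes rose and none fell in F2 (median log2 fold change 0.49, adjusted p = 3.38e-09, limma cameraPR). Adjusted over the list alone, 12 rose and none fell. In the authors' deposited table sqle rose from 0.232 to 3.32 FPKM (log2 fold change 3.84, q = 0.0207), msmo1 by 2.32 and cyp51a1 by 1.74. Of the other called members, fdft1 and hsd17b7 had 1.05 and 0.99 in the authors' deposited table. Hormone-sensitive lipase, lipe, went from 2.08 to 19.4 FPKM in the authors' deposited table (log2 fold change 3.22, q = 0.00755). For cyp7a1 the F2 value in the authors' deposited table was -0.11 (q = 0.997).

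**Figure D1:**
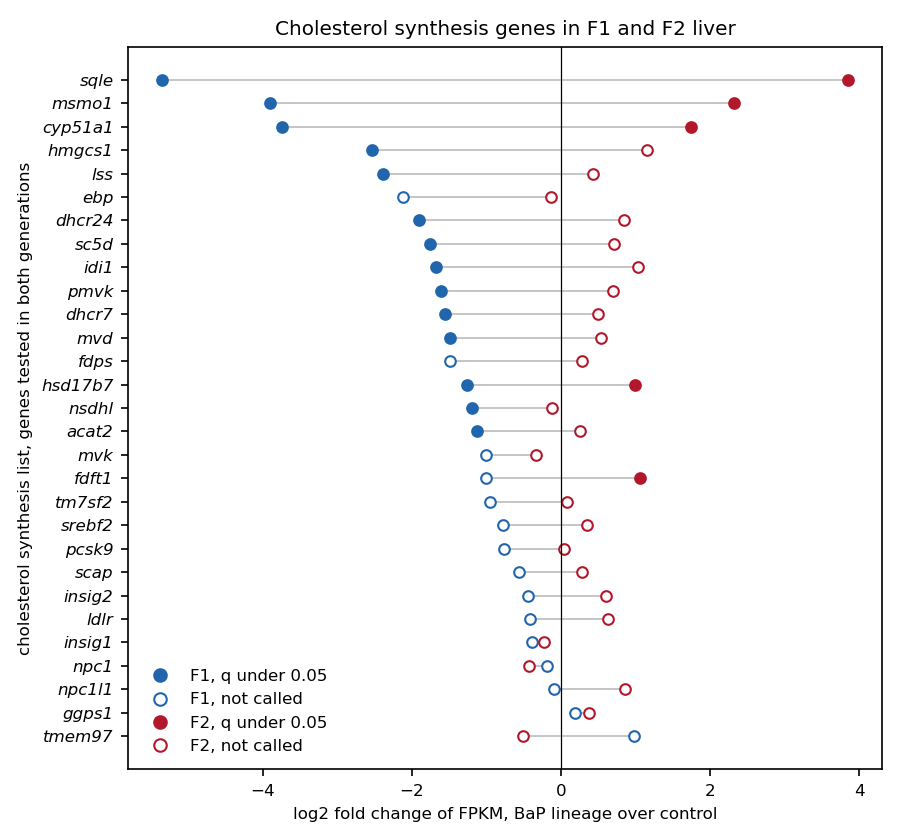
Log2 fold change of FPKM (BaP over control, horizontal axis) of 29 cholesterol synthesis genes tested in both generations, in F1 (blue) and F2 (red), from the authors' deposited tables; filled points have q under 0.05. All filled points lie to the left of 0 in F1 and to the right of 0 in F2, with sqle at -5.34 and 3.84.

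Among the F2 falls in the authors' deposited table, fos fell from 9.85 to 1.09 FPKM (log2 fold change -3.17, q = 0.00755), egr1 had -2.13, dusp1 -2.09 and nr4a1 -1.96. The first 3 of these were the called members among 39 genes of the inflammatory cytokine and NF-kB list (median -0.07, adjusted p = 0.0396, limma cameraPR), whose call was lost at a preset correlation of 0.05 (adjusted p = 0.277) and against random lists matched on expression (adjusted p = 0.714). The matricellular protein genes ccn1 and ccn2 had -2.41 and -1.28 in the authors' deposited table, and with tagln (-0.86) they were the 3 called genes, all lower, of 39 in the stellate cell and matrix list (list adjusted p = 0.873). The growth factor gene igf1 went from 19.3 to 6.15 FPKM in the authors' deposited table (log2 fold change -1.65, q = 0.00755), and rgs4 had -2.39.

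Acute phase genes included 3 rises among 68 tested in F2: the lectin gene fcn1 (1.73) and the pentraxin genes crp.4 (2.03) and apcs (1.96) in the authors' deposited table (list adjusted p = 0.918, limma cameraPR). Oxidative phosphorylation genes fell as a list, with 61 of 74 values below 0 and a median of -0.23 (adjusted p = 0.00352), as did urea cycle and amino acid genes, with 45 of 60 values below 0 and a median of -0.22 (adjusted p = 0.00415), and heat shock genes, with 32 of 41 values below 0 and a median of -0.17 (adjusted p = 0.0156). Cuffdiff called 0 genes in these 3 lists, and 3, 8 and 2 members were lower at an unadjusted p under 0.05. All 3 lost their call at a preset correlation of 0.05 (adjusted p = 0.183, 0.183 and 0.231). Fold changes in F2 fell with expression, to a median of -0.17 for 382 genes outside the ribosomal and oxidative phosphorylation lists at 100 to 1000 FPKM, and random lists matched to oxidative phosphorylation had a median of -0.13 (adjusted p of the list against them 0.0376). Against random lists matched on expression, the urea cycle list kept its call (adjusted p = 0.00533) and the heat shock list lost it (adjusted p = 0.0794).

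Pancreas markers were higher in F2 as well (6 of 8 values above 0, median 0.69, adjusted p = 0.00415, limma cameraPR), with 0 called by Cuffdiff, 3 at an unadjusted p under 0.05 and 3 when adjusted over the list alone. With ranks in place of z this call was lost (adjusted p = 0.0511). For ctrc the authors' deposited table gave a log2 fold change of 4.03 and q = 0.0556. Pigment cell markers were lower (5 of 6 values below 0, median -0.54, adjusted p = 0.0156, and 0.0704 at a preset correlation of 0.05), and the melanosome gene pmel was called with -1.52 in the authors' deposited table. Of the skeletal muscle markers, acta1 was called with -1.77 in the authors' deposited table (list adjusted p = 0.0713). Without the 7 lists of other tissues, 157 genes were called in F2, 95 higher and 62 lower.

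The other large F2 changes in the authors' deposited table were rises of lrrc43 (3.63), lrrc26 (2.53), tgm4 (2.52), tm4sf18 (2.49) and ap1m2 (2.21) and falls of cdh10 (-1.91), slc26a9 (-1.81) and svopl (-1.73). In the xenobiotic oxidation list 1 of 38 genes was called, higher, while 25 values were below 0 (list adjusted p = 0.148, and 0.0453 as lower among genes reaching 1 FPKM), and cyp1a1 had a log2 fold change of -0.33 and ahr of -0.25 in the authors' deposited table for F2. The estrogen receptor gene esr1 had -0.09 in F1 and -0.10 in F2, the nuclear receptor gene ppara 0.88 and 0.37, the fatty acid synthase gene fasn 0.29 and -0.13, the DNA methyltransferase gene dnmt1 -0.05 and 0.35 in the authors' deposited table, none with q under 0.05. The insulin receptor gene insr, tested in F2 but not in F1, had -0.43. In all, 7 of 40 lists passed in F2, 2 of which, cholesterol synthesis (adjusted p = 0.000112) and pancreas (adjusted p = 0.0334), also passed at a preset correlation of 0.05.

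**Figure D2:**
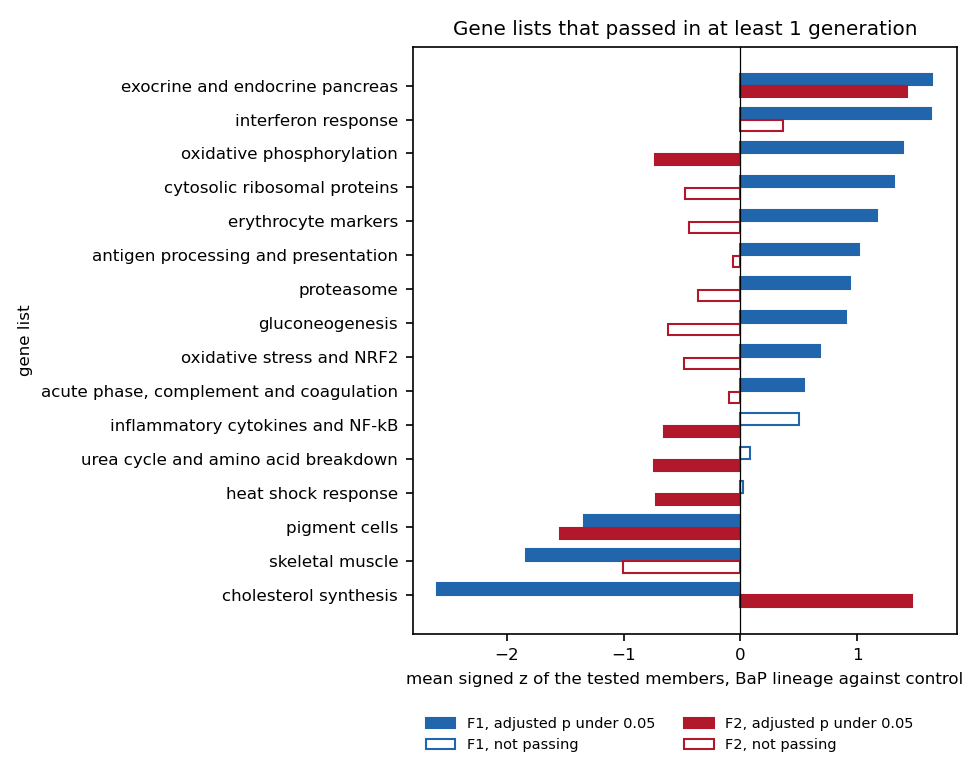
Mean signed z of the tested members (horizontal axis) of each of the gene lists that passed in at least 1 generation, in F1 (blue) and F2 (red); filled bars have a limma cameraPR adjusted p under 0.05. The cholesterol synthesis bars point in opposite directions, at -2.59 in F1 and 1.47 in F2, while the pancreas bars, at 1.64 and 1.43, point the same way.

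The generations were next compared with each other. A small set of genes was called in the same direction in both, and cholesterol synthesis genes changed in opposite directions. Of 11679 genes tested in both tables, 26 were called in both, 17 in the same direction and 9 in opposite directions. The p-values that follow treat genes as independent. Genes of 1 pathway or 1 stretch of the genome may not be, so these p-values can overstate the evidence. Higher in both were 14 genes, where 0.515 would be shared by independent lists (p = 6.05e-17, Fisher's exact test, one-sided), and 3 were lower in both, against 0.565 (p = 0.0189, Fisher's exact test, one-sided). Lower in F1 and higher in F2 were 9 genes, against 0.885 (p = 2.29e-07, Fisher's exact test, one-sided), and 0 genes were higher in F1 and lower in F2, against 0.329 (p = 1, same test).

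Among the genes shared in direction, the secreted protein gene msmb.1 had log2 fold changes of 2.30 and 2.13 in F1 and F2, igfbp1 2.40 and 1.52, emilin1 1.44 and 1.22, tap1 1.38 and 1.09 and muc2 1.27 and 1.74 in the authors' deposited tables. The galactose metabolism gene galt had -1.46 and -1.20, and the actin gene acta1 -3.39 and -1.77 in the authors' deposited tables. Rows with a LOC identifier or several genes made up 10 of the 17, or 58.8%, against 11.9% of all genes tested in both, but such rows were frequent among calls in general: 133 of 207 calls in F1 and 104 of 162 in F2 had 1 gene symbol. The largest was LOC100494627 (chromosome 7, 132086238 to 132089456), at 4.28 in F1 and 4.40 in F2 in the authors' deposited tables. It lies beside the pancreas elastase gene cela3a (chromosome 7, 132106352 to 132109595; chosen after its values were seen), at 6.82 and 3.17 there, with q = 0.945 and 0.0953 in the authors' deposited tables, and pancreas markers as a list were higher in both generations. Without members of the lists of other tissues, an alternative chosen after seeing the data, 15 were called in the same direction and 8 in opposite directions. LOC108648819 (2.95 and 2.51), LOC100488697 (2.37 and 2.86) and LOC100497740 (2.11 and 1.83) followed in the authors' deposited tables. For 15 of the 17 genes the log2 fold changes of F1 and F2 lay within 0.5 of each other, and for 0 of them did the test of the difference pass (normal test with Benjamini-Hochberg adjustment), a test that misses many true differences. Both counts are partly fixed by choosing genes called in the same direction in both, so they are no separate evidence of agreement. The widest gaps were 1.61 for acta1 and 0.89 for igfbp1. Among the 26 genes called in both, 13.8 would share direction if directions were independent (p = 0.0846, Fisher's exact test, one-sided, chosen after seeing the data).

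The 9 genes that were lower in F1 and higher in F2 included sqle, msmo1, cyp51a1 and hsd17b7 of cholesterol synthesis, lipe, the acetate-activating enzyme gene acss2.2, the transglutaminase gene tgm4 and the sorting adaptor gene ap1m2. In the authors' deposited tables acss2.2 had -2.34 and 1.17, tgm4 -3.25 and 2.52 and ap1m2 -1.09 and 2.21. For msmo1 the authors' deposited tables list 58.5 and 3.92 FPKM in F1 control and BaP livers and 8.85 and 44.2 in F2, but the 2 tables were normalised separately, so levels are not compared across them.

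**Figure D3:**
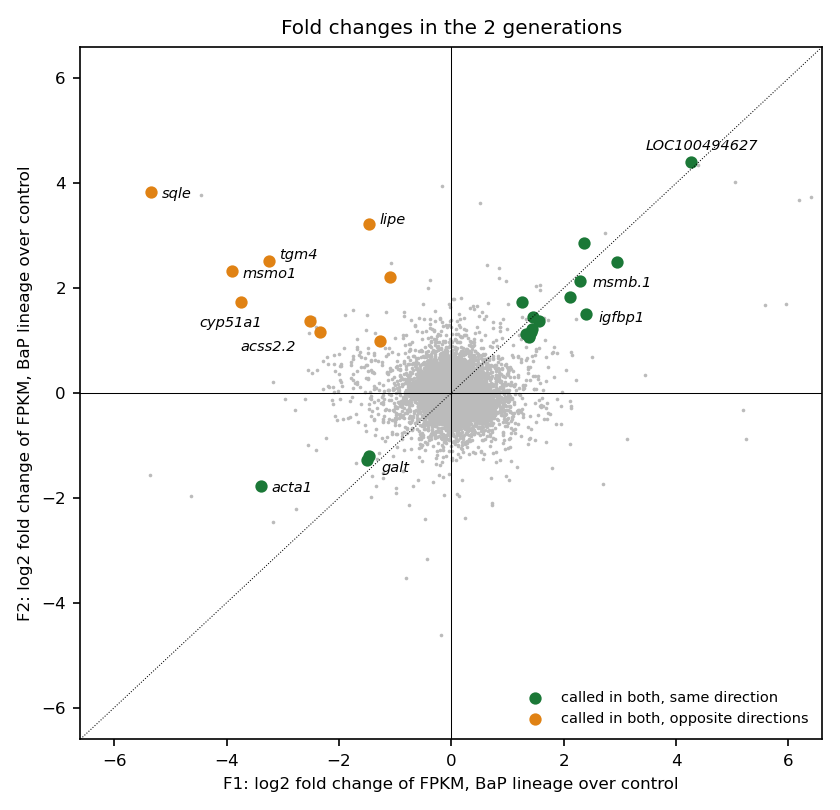
Log2 fold change of FPKM (BaP over control) in F1 (horizontal axis) and F2 (vertical axis), from the authors' deposited tables, for genes reaching 1 FPKM in a group of each table (grey; 4 lie outside the axes) and for the genes called in both generations. Of the 17 called in the same direction, 15 have fold changes within 0.5 of each other (dotted line, equal change), and the 9 called in opposite directions lie at the upper left.

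Tested directly, the change differed between generations for 112 of 11677 genes (adjusted p under 0.05), with F2 above F1 for 69 and below for 43. Cholesterol synthesis held 14 of the 69, among its 30 genes tested in both. As a list it differed with an adjusted p of 2.08e-36 (limma cameraPR on the difference), and 11 of 40 lists differed in all. With standard errors taken from the deposited test statistic, which are larger, 1 gene, msmo1, kept an adjusted p under 0.05. With these standard errors, 9 of the 11 lists differed, cholesterol synthesis among them (adjusted p = 1.55e-49, limma cameraPR). This is not a stricter test of the lists. Because cameraPR weighs a list against the spread of z over all genes, an enlargement shared equally by all genes would leave its p unchanged. The enlargement was not equal for all genes, since the adjusted p became smaller for cholesterol synthesis and larger for skeletal muscle (0.0407 and 0.0678, limma cameraPR). Across 10367 genes, which are not independent replicates, the fold changes of the 2 generations had a Spearman rho of -0.11 and a Pearson r of 0.03, of opposite sign, and rho was 0.21 among 199 genes with an unadjusted p under 0.05 in both.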

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

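Of the tests of the 3 patterns weighed below, the random lists for cholesterol synthesis were planned as an alternative, though set against scaling only later, and the count of columns with single libraries was set beforehand, while the tests of chromosomes, shuffled overlap, shared direction, neighbouring genes, composition and shuffles within classes of FPKM and span were chosen after the values they bear on had been seen. The shuffles took the place of random lists matched on gene span, a test written before its result, because such lists match ribosomal proteins poorly, and the list differences with the test statistic were also added later.

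The change between the control and BaP lineages differed between F1 and F2 for 112 genes and, by limma cameraPR on the difference, for 11 gene lists. With standard errors from the test statistic, 1 gene, msmo1, was left of the 112. F2 lay above F1 for cholesterol synthesis (adjusted p = 2.08e-36) and skeletal muscle (adjusted p = 0.0407). It lay below F1 for oxidative phosphorylation (adjusted p = 7.35e-15), ribosomal proteins (adjusted p = 2.11e-12), erythrocyte markers (adjusted p = 3.36e-05), gluconeogenesis (adjusted p = 3.62e-05), the interferon response (adjusted p = 4.24e-05), the proteasome (adjusted p = 0.000238), oxidative stress and NRF2 (adjusted p = 0.00156), inflammatory cytokines and NF-kB (adjusted p = 0.00577) and the unfolded protein response (adjusted p = 0.0412). Skeletal muscle and the unfolded protein response missed the threshold with standard errors from the test statistic (adjusted p = 0.0678 and 0.0649). Some of these differences were not reversals. Skeletal muscle medians were -1.17 in F1 and -0.40 in F2, and interferon response medians 0.86 and 0.12. In F2, 24 of 36 interferon response values were above 0 (list adjusted p = 0.148, limma cameraPR, and 0.0422 against random lists matched on expression). Fold changes rose with expression in F1 and fell with it in F2, a trend that these tests do not remove.

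Of the genes named by rule or called in both generations, 19 of 78 differed between generations. The log2 fold change in F2 minus that in F1 was 9.19 for sqle, 6.22 for msmo1, 5.78 for tgm4, 5.49 for cyp51a1, 4.68 for lipe, 3.68 for hmgcs1, 3.55 for tm4sf18, 3.51 for acss2.2, 3.38 for pbxip1, 3.30 for ap1m2, 2.25 for hsd17b7 and 2.23 for slc27a4. It was -5.51 for pck1, -4.44 for svopl, -4.01 for mx1, -2.86 for egr1, -2.39 for mr1-like, -2.21 for vnn1 and -1.51 for hbd. With standard errors from the test statistic, only msmo1 of these kept its call.

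Cholesterol synthesis genes fell in F1 and rose in F2. A scaling difference between groups is argued against, because the list median lay outside random lists matched on expression in both generations (permutation p = 0.0002 in each, the smallest these lists can give). A difference in 1 stretch of the genome that changed only the genes within it is argued against too: the called F1 members lie on 7 chromosomes. A stretch that acts on genes elsewhere stays open, since a count of chromosomes cannot show it. Single frogs that set the group value stay open, since 0 columns hold values of single libraries. A true effect of ancestry that turns with generation, or a different state of the frogs at sampling, also stays open and was not tested here beyond the fasting list among the other observations.

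The 17 genes called in both generations in the same direction are too many for 2 independent lists of independent genes, since the highest number in 10000 shuffled lists was 7. Shuffled lists treat genes as independent, so groups of genes that vary together stay open. Genes prone to be called in any comparison also stay open. The directions of the 26 genes called in both went together by a margin that missed the threshold (p = 0.0846, Fisher's exact test, one-sided). Inherited sequence differences between the 2 lines of frogs are a candidate explanation that stays open, since they would gather such genes in stretches of the genome. Of the 17, 4 had another of the 17 within 1 Mb, against a median of 0 both in random sets of tested genes (permutation p = 0.034, one-sided) and in sets of genes called in either generation (permutation p = 0.0709, one-sided). Calls were clustered in general (87 of 207 in F1 against a median of 64 and 67 of 162 in F2 against 40, permutation p = 0.004 and 0.000999), and reads shared between similar neighbours such as LOC116406581 and LOC100495542 could also give such pairs. An effect of the exposure passed on to both generations was not told apart from descent, because the labels do not say how many F0 parents founded each lineage.

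Ribosomal protein and oxidative phosphorylation genes were higher in F1. A trend with expression level is argued against as the whole cause for oxidative phosphorylation genes. Shuffling list membership within doublings of FPKM gave a central 95% range of 0.02 to 0.24 for their median of 0.47 (permutation p = 0.0002). For the ribosomal median of 0.71 the range was 0.63 to 0.68 (permutation p = 0.0002). Ribosomal genes outnumber others at the highest levels, however, so shuffled lists there were drawn mostly from the list itself. The shuffles also treat genes as independent, which genes of 1 complex may not be. Gene span is argued against likewise for oxidative phosphorylation genes, with a range of 0.10 to 0.32 within classes of FPKM and span (permutation p = 0.0002). The ribosomal range was 0.64 to 0.68 there (permutation p = 0.0002), with the same limit. Medians of ribosomal and other genes were 0.92 and 0.36 at 1000 to 2000 FPKM (9 and 27 genes), 0.80 and 0.32 at 2000 to 4000 (18 and 15) and 0.68 and 0.56 above that (48 and 8). Expression level and span thus stay open as causes for the 48 ribosomal genes above 4000 FPKM. A shift of composition by genes without a value would move all genes alike. The median of tested genes with at least 1 FPKM was 0.0260, so no such shift was left in the deposited fold changes. Whether composition differed cannot be told, because a scaling that centres fold changes would give this median too, and the scaling is not stated. RNA quality and single frogs stay open, because neither can be seen without libraries.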

How the results depend on the processing

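Leaving out other tissues, scaling the difference and using the test statistic for lists were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the tables hold group values and no library with a replicate number. For the same reason leaving out single frogs, a replicate block and other splits of the samples were not run. After centring, all called named genes kept their direction, which this setting could not change. The medians taken off were 0.0260 in F1 and -0.0360 in F2, and the smallest called changes were 1.02 and 0.84 in size. All 171 comparisons of a named gene under recomputed q kept their side of the threshold, but at q under 0.01, 37 of 71 named calls with a finite fold change stayed in F1 and 28 of 46 in F2. Calls in F1 went from 207 to 95 at q under 0.01, 315 at q under 0.1 and 133 among rows with a single symbol, and calls in F2 from 162 to 81 at q under 0.01 and 104 among rows with a single symbol, as the construction of these settings implies. All other settings gave 196 to 207 calls in F1 and 157 to 234 in F2. Genes called in both in the same direction went from 17 to 9 at q under 0.01, 26 at q under 0.1 and 125 at an unadjusted p under 0.05 in both, and those in opposite directions from 9 to 1, 12 and 97 (at unadjusted p, 41.3 and 41.2 expected). Spearman's rho of -0.11 became -0.23 at a minimum FPKM of 10 and 0.21 among genes with an unadjusted p under 0.05 in both, and the cause was not tested. Genes that differed between generations went from 112 to 204 at an adjusted p under 0.1, to 1 with the standard error from the test statistic, which is about 2.29 times larger, and to 176 when that z was scaled to its own spread, 108 of them among the 112. Lists passing in F2 went from 7 to 2 at a preset correlation of 0.05 and 11 against random lists, and the cause was not tested beyond the larger assumed correlation. Over all lists and alternatives, 365 comparisons kept their side, 15 lost a call and 18 gained one. Centring z was among these alternatives and cannot change a cameraPR p, so its comparisons were kept by construction. The q cannot go below 0.00654 in F1 and 0.00755 in F2, so calls at this floor cannot be ranked by q.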

Other observations

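The lists of motile cilium, immediate early and fasting genes and their tests were all written after the calls had been seen. The tests below leave out genes called in the generation where the pattern was first seen, or in either generation for fasting genes. They were run only at the main preset correlation between genes, and the alternative of 0.05 was not tried on them. Some of the lists set in advance lost their call at that alternative, so whether the p-values below would hold there is not known.

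Genes of the motile cilium, the beating organelle of multiciliated cells, were lower in F1 BaP livers. Of 84 tested genes 79 had a negative log2 fold change, 20 were called, all lower, and the median was -1.20. The axonemal dynein genes dnah9 and dnah1 had -3.05 and -1.72, spag17 had -2.10 and ccdc181 had -2.01 in the authors' deposited table. These were chosen after their values were seen and are among the lower-expressed ones: control values of the 20 called genes ran from 0.793 FPKM for spag17 to 17.7 for crocc (log2 fold change -1.54) in the authors' deposited table. A hypothesis is that these genes as a group were lower in F1 BaP livers, as fewer ciliated cells or a weaker ciliary program would give. It was tested on the 64 genes that were not called, which also were lower than other genes (limma cameraPR, n = 64 genes, p = 1.6e-20). Because these values come from the same frogs, the test cannot tell fewer cells from a weaker program or from single frogs. In F2 the direction was the other one, with 61 of 76 values above 0 and a median of 0.29. The list without genes called in F1, which keeps lrrc43, called in F2, was higher in F2 than other genes (limma cameraPR, n = 61 genes, p = 0.000454). These genes thus moved in the same 2 directions as cholesterol synthesis genes, and which cells of the liver sample carried them was not analysed here.

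Immediate early genes, which respond within minutes to growth factors, stress and handling, were frequent among the F2 falls: 8 of 42 tested were called lower and 1, per1, was called higher. A hypothesis is that these genes as a group were lower in F2 BaP livers. It was tested on the 33 genes not called, which were lower than other genes (limma cameraPR, n = 33 genes, p = 0.000412). In F1 the direction was the other one: the median of 38 genes was 0.21, with 29 values above 0, and the list without genes called in F2 was higher than other genes (limma cameraPR, n = 30 genes, p = 0.00754). The time between capture and freezing of each frog is not given in the labels, so handling could not be set against ancestry.

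Gluconeogenesis genes had medians opposite in sign to those of cholesterol synthesis genes, 0.19 in F1 and -0.22 in F2, although the F2 list did not pass (adjusted p = 0.0724). A difference in feeding between the groups at sampling is a candidate explanation, since fasting raises the former and lowers the latter in vertebrate liver. It was tested on 26 other genes raised by fasting, none of them called in either generation. These had a lower F2 minus F1 difference than other genes by a margin that missed the threshold (limma cameraPR, n = 26 genes, p = 0.0824), so feeding cannot be told apart from an effect of ancestry with these data. Taken by generation, p was 0.507 in F1, with a higher mean, and 0.0599 in F2, with a lower one (limma cameraPR against other genes, n = 26 genes). Single genes raised by fasting point both ways: pck1 (5.19 in F1 and -0.32 in F2) and ddit4 (1.95 and -0.59) go with feeding, while igfbp1 (2.40 and 1.52) and per1 (-0.23 and 1.13) in the authors' deposited tables do not, of which ddit4 and per1 were chosen after their values were seen.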
